A study of Gallus gallus with 6 samples.

How the data were processed

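Gene expression had been measured on 6 one-colour Affymetrix Chicken Genome arrays, 3 with RNA of cultured primordial germ cells (PGC) and 3 with RNA of cultured embryonic fibroblasts (CEF). Groups and replicate numbers were taken from the sample titles, which call the replicates biological. Per the labels' protocols, total RNA was isolated with a Qiagen RNeasy kit, treated with RQ1 DNase and labelled as biotinylated cRNA, with about 5 µg of RNA for each array. Values for 38535 probe sets had been deposited, and were taken to be log2 expression already normalized between arrays. The submitters' processing notes name MAS5 and GCOS, and their roles, their versions and the steps of normalization and background correction are not given in the sources used here. The log2 scale was itself read from the deposited values, which ran from -0.13 to 12.52. On this scale the bacterial hybridisation spike-ins spanned 6.24 from bioB to cre on the PGC arrays and 5.26 on the CEF arrays, and this span alone does not settle the base. All folds rest on the reading as base 2. The deposited values had a similar distribution on the 6 arrays, so a difference in the total amount of RNA per cell between the 2 cell types would not be seen.

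The values were used with no further scaling. The 96 AFFX control probe sets were left out of the tests, which left 38439 probe sets, 57 reporter probe sets among them. In the table of probe set annotation used here, 27178 probe sets had 1 gene symbol, 177 had several and 11180 had none, and no gene was named from a probe set with several. Each of 13009 genes was represented by its probe set with the highest mean over the 6 arrays. Gene symbols are those of the array annotation, and chromosome positions were not used here because that annotation comes without a matching genome.

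PGC and CEF were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with the cell type as the only term. All p-values were adjusted with the Benjamini-Hochberg method over the 38439 probe sets. A probe set or gene was called at an adjusted p under 0.05 with at least a 2-fold difference, that is an absolute log2 difference of at least 1. Differences are given as PGC minus CEF on the log2 scale with their standard errors from limma, and levels as mean and SD over 3 arrays. The design left 4 residual degrees of freedom, and the number of arrays limits the precision.

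A background level was set for each cell type at the 95th percentile of 712 probe sets, a choice made after seeing the data. They comprised 689 probe sets whose identifiers lack the prefix of the array's chicken probe sets, 2 of them with a gene symbol, and blank reporter probe sets. The level averaged 1.68 on the PGC arrays and 1.97 on the CEF arrays. Where the lower cell type of a gene lay under its background level, the fold is given as "at least N-fold", computed from the mean of the higher cell type against that background level. The log2 difference printed for such a gene is that of the deposited values and is not an exact size. At the bright end, 91 genes, 26 of them called, had a mean above that of the spike-in cre in a cell type (11.20 in PGC, 11.33 in CEF), where saturation is not excluded.

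Gene lists for 33 pathways and cell types were fixed before the data were examined, together with the tests, the rule for naming genes and most alternatives. The lists covered germ cell identity, the piRNA pathway, meiosis, pluripotency, extracellular matrix, fibroblast and mesenchyme markers, the actin cytoskeleton and HOX genes. Signalling was covered by lists for FGF, for TGF-beta, activin and BMP, for WNT and for the IGF axis. Further lists held genes of G2/M, DNA replication, CDK inhibitors and growth arrest, DNA methylation and chromatin, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, the pentose phosphate pathway with nucleotide synthesis, cholesterol, ribosomal proteins, innate antiviral defence and heat shock with the unfolded protein response. Markers of other cell types were listed for erythroid cells, leukocytes and thrombocytes, endothelium, muscle, neural and neural crest cells, cartilage and bone, epithelium and gonadal or liver somatic cells, and W-linked genes made the last list. Of 1024 list entries, 841 matched a symbol, 30 matched only through a synonym and 153 were not matched. A synonym match need not be the same gene. Those of ALAS1 to ALAS2, SH2D6 to BLNK and LOC770612 to IFITM3 are doubtful, but were kept in the counts. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over 32 lists. Camera with the correlation estimated per list and fry, which asks only whether a list's own genes move one way on balance, served as alternatives.

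Genes were named by 4 rules. The first took the 12 largest differences in each direction among called genes whose 3 arrays of the higher cell type all lay above the other 3 and whose higher mean exceeded the 75th percentile of all values, 5.09, leaving out probe sets shared between transcripts and symbols that are only clone or open reading frame names or LOC numbers. The second took from each list up to 4 called members with the largest differences and up to 2 called members that went against most of the list. The third named DDX4, DAZL, NANOG, POU5F3, KIT, CXCR4, COL1A1, COL1A2, FN1, VIM, TWIST1, GPI and GAPDH, of which NANOG and POU5F3 had no probe set with that symbol alone and were not analysed here. The fourth took the 2 members with the highest mean from lists that were not called. A few further genes are named to complete a count of 5 or fewer or to give the measured members of a family, and those were chosen after their values were seen. They are LAMB1, SLC16A1, PFKP, MYB, PTPRC, SPI1, CSF1R, KRT14, SDF2L1, HSPB9, HAPLN1, TDG, MBD2, IGFBP3, IGF1R, IGFBP7, IGF2BP1, the globins, SOX2, ESRP2, C8orf22 and the W-linked genes. One leukocyte list member that the second rule takes is not reported here.

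The same code was tested on simulated values for all 38439 probe sets. Of 100 probe sets changed by 1.5 on the log2 scale 85 were called, of 100 changed by 3 on the log2 scale 99 were called, and 3 of 38239 unchanged probe sets were called. In the simulation camera found a shifted list of 30 probe sets and called 0 of 100 unshifted lists. The simulated probe sets varied independently, so this does not test how correlation between genes affects the list calls. Both cell types were given the same SD for a probe set, whereas CEF replicates varied more in the data. Far fewer probe sets were changed than were called in the data, so the rates of recovery need not hold there. The shared replicate numbers of the titles were checked and do not pair the arrays. Alternatives fixed in advance were quantile normalization, centring on the 75th percentile, an offset of the 10th percentile before the logarithm, leaving out probe sets dimmer than the median, no intensity trend, a replicate block, leaving out each array, limma's treat against a 2-fold difference, no minimum fold, the mean of a gene's probe sets, the estimated correlation and fry. Scaling to the bacterial hybridisation spike-ins bioB, bioC and bioD and limma's array weights were added after seeing the data.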

Results

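The data compared cultured chicken primordial germ cells (PGC), the embryonic precursors of eggs and sperm, with cultured chicken embryonic fibroblasts (CEF), connective-tissue cells that can be grown from the embryonic body. The series was made to find transcripts that are mainly expressed in one or the other of these cultured cell types. PGC had been grown from blood of embryos at day 2.5, from 20 embryos per replicate, in knockout DMEM with 10 ng/ml human basic fibroblast growth factor. For each RNA sample 1500000 cells were used. CEF had been grown from embryos at day 6.5 with internal organs and limbs removed, from 5 embryos per replicate, in DMEM with 10% fetal bovine serum. At passage 2, 6000000 cells were used. Embryonic age, medium and cell type therefore changed together. Each cell type had 3 arrays. Median log2 expression lay between 2.69 and 2.77 on the 6 arrays, and between 63.2% and 68.2% of probe sets were above the background level.

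Arrays of one cell type resembled each other more than arrays of different cell types. The correlation across probe sets was 0.997 for each pair within PGC, between 0.980 and 0.987 within CEF and between 0.850 and 0.862 across the cell types. Probe sets are not independent replicates. CEF replicates varied more, with a median SD of 0.203 against 0.0953 in PGC, a ratio of 2.13.

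Higher in PGC were 13 of 19 measured germ cell identity genes, 12 of 21 pluripotency genes, 19 of 30 G2/M genes and 21 of 33 DNA replication genes. Higher in CEF were 39 of 47 measured extracellular matrix genes, 23 of 26 actin and contractile genes and 21 of 33 mesenchyme markers. These 7 lists were called by limma's camera with a preset correlation between genes, and none of them was with an estimated correlation (adjusted p between 0.055 and 0.38). DAZL, an RNA-binding protein of germ cells, was at least 659-fold higher in PGC (log2 difference 10.27 ± 0.15), and DDX4, the germ cell helicase VASA, was at least 464-fold higher (9.43 ± 0.13), both with an adjusted p of 2.3e-09. POSTN, which encodes the matrix protein periostin, was at least 527-fold higher in CEF (-10.27 ± 0.12, adjusted p = 1.5e-09). COL1A1, the alpha-1 chain of type I collagen, was 250-fold higher (-7.97 ± 0.11). GAPDH, a glycolytic enzyme often used as a reference, had a log2 difference of -0.02 ± 0.05 (adjusted p = 0.81), which turned to 0.96 when arrays were scaled to the bacterial spike-ins and to 0.00095 and 0.028 without PGC replicate 1 and CEF replicate 3. GPI, of the same pathway, had one of 0.26 ± 0.04, under the 2-fold minimum, or 1.23 after that scaling. GAPDH, at 11.99 in PGC, and COL1A1, at 12.10 in CEF, were brighter than cre, the brightest bacterial spike-in, for which saturation is not excluded and would hide or understate a difference. The same holds for FN1, COL1A2, VIM, CCN2, CSRP2, TAGLN, LGALS1A, DAZL, ENS-3, CLDN1, HSP90AA1, HSPA8 and ENO1. Cre itself differed by only -0.13 between the cell types, so spike-in scaling may overstate the shift of genes this bright.

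With limma and Benjamini-Hochberg adjustment, 9469 of 38439 probe sets (24.6%) differed, 5597 higher in PGC and 3872 higher in CEF. By the brightest probe set of each gene, 4227 of 13009 genes (32.5%) were called, of which 2294 were higher in PGC and 1933 in CEF. At least 8-fold differences were found for 281 genes in PGC and 482 in CEF, and 662 called genes lay at background in the lower cell type. The 3 arrays of one cell type all lay above the 3 of the other for 9465 of the called probe sets, and for 59.8% of all probe sets where chance gives 10%. Of 7334 genes with several probe sets, 52 had probe sets called in opposite directions. With the mean of all its probe sets in place of the brightest, the calls ended for SPRED1 (-0.69), BMP7 (0.87), IRS2 (0.71), MCM10 (0.95), PRIM2 (-0.70), TET2 (-0.36), IDH2 (-0.33), SUCLG2 (0.78), ADSS2 (0.97), IFNGR2 (-0.93), TFRC (-0.29), PFKP (-0.87) and AMH (0.081), and TF (-0.062) and UBAP2L2 (-0.087) turned sign. With limma's treat, which tests against a 2-fold difference, the calls of 31 named genes ended (adjusted p between 0.053 and 1). Those higher in PGC were MEI1, FBLN2, LAMB1, LEF1, IGFBP7, IGF2BP1, RBL1, FBP1, SLC16A1, ADSS2, IRF8, CA2, CYBB, MYB, SOX9, AMH, TF and UBAP2L2. Those higher in CEF were SPRED1, PRIM2, TET2, HDAC4, TDG, MBD2, IGF1R, IDH2, PFKP, CSF1R, SDF2L1, HSPB9 and HAPLN1.

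The balance between the directions depended on the scaling. Of the called probe sets 59.1% were higher in PGC with the deposited values, and 89.8% after scaling to the bacterial hybridisation spike-ins. These controls, bioB, bioC and bioD, were lower on the PGC arrays by a mean log2 difference of -0.97. The brighter control cre, left out of that scaling, differed by only -0.13. For genes near or above the level of cre the scaling may overstate the shift. That scaling moved the median difference of all probe sets from -0.09 to 0.89, and centring on the 75th percentile moved it to -0.21, so that differences are relative to these medians. Calls towards CEF ended under spike-in scaling for SPRED1 (-0.35), PRIM2 (-0.14), TET2 (-0.47), HDAC4 (-0.26), IDH2 (-0.19), NDUFS3 (-0.68), PAICS (-0.53), IFNGR2 (-0.73), TFRC (-0.65), PFKP (-0.070), CSF1R (-0.15), SDF2L1 (-0.58), HSPB9 (-0.46), HAPLN1 (-0.41), TDG (-0.049), MBD2 (-0.039), IGFBP3 (-0.96) and IGF1R (-0.43). Calls towards PGC were gained for STAG3 (1.18), MSH4 (1.40), FGFR2 (1.65), ENO1 (1.16), GPI (1.23), MDH2 (1.27), COX4I1 (1.44), HSPA8 (1.20), SOX17 (1.63), FABP7 (1.75) and COL2A1 (1.12). Of 32 gene lists tested, 17 were called by camera, 7 higher in PGC and 10 in CEF. With an estimated correlation camera called 0 lists (8 at an unadjusted p under 0.05), and fry called 31. Where limma called 0 members of a list towards CEF, 2 germ cell identity, 1 piRNA, 4 meiosis, 1 G2/M, 7 ribosomal protein and 1 W-linked gene had an unadjusted p under 0.05 in that direction. Where it called 0 towards PGC, 1 mesenchyme, 0 actin, 0 HOX and 27 ribosomal protein genes had one. Counts adjusted over the list alone equalled those over all probe sets in every list except extracellular matrix, TGF-beta and innate antiviral defence.

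**Figure D1:**
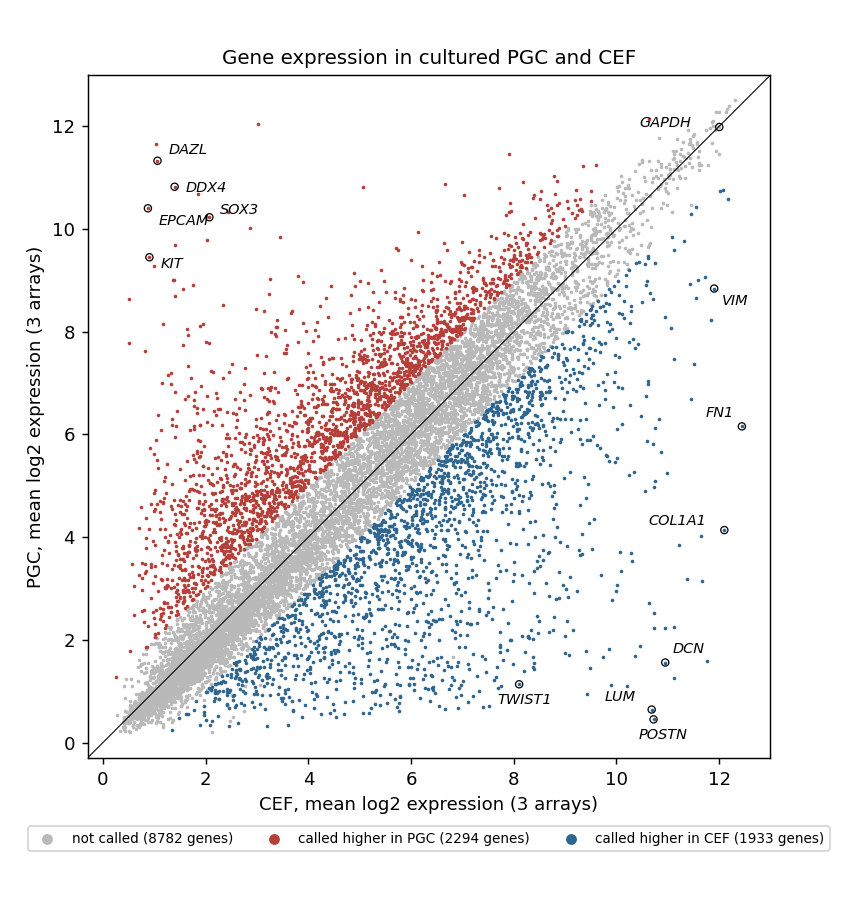
Mean log2 expression of 13009 genes in CEF (x axis) and PGC (y axis), each over 3 arrays, with 2294 genes called higher in PGC in red, 1933 called higher in CEF in blue and the others in grey. Germ cell genes such as DAZL and DDX4 lie at the upper left, matrix genes such as POSTN, LUM and DCN at the lower right, and GAPDH on the diagonal of equal expression.

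Of 19 measured germ cell identity genes, 13 were higher in PGC, 0 were higher in CEF and 6 were not called (camera adjusted p = 2.5e-05; adjusted p = 0.064 with an estimated correlation; 13 adjusted over the list alone). Besides DAZL and DDX4 they included KIT, the receptor of stem cell factor, at least 179-fold higher (8.55 ± 0.18), and DMRT1, a transcription factor of the germ line and of male gonads, at least 133-fold higher (7.65 ± 0.18). CXCR4, the chemokine receptor that guides migrating germ cells, was 24.5-fold higher (4.61 ± 0.52, adjusted p = 9.5e-05). DAZL averaged 11.33 ± 0.02 (SD, n = 3) in PGC and 1.06 ± 0.27 in CEF, under the CEF background level of 1.97.

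The piRNA pathway, which silences transposable elements in germ cells, had 13 of 17 measured genes higher in PGC, 0 higher in CEF and 4 not called (camera adjusted p = 1.7e-05; adjusted p = 0.099 with an estimated correlation; 13 adjusted over the list alone). PNLDC1, the exonuclease that trims piRNA ends, was at least 72.9-fold higher (6.22 ± 0.22). TDRD1, a tudor-domain protein, was 33.5-fold higher (5.07 ± 0.17), the helicase MOV10L1 at least 18.7-fold (4.85 ± 0.15) and PIWIL1, which binds the piRNAs, 26.5-fold (4.73 ± 0.26).

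Of 20 measured meiosis genes, 8 were higher in PGC and 12 were not called, 7 of the 20 lying at background in both cell types. The list was not called by camera (adjusted p = 0.17; adjusted p = 0.38 with an estimated correlation; 8 genes adjusted over the list alone). HORMAD1, a protein of the meiotic chromosome axis, was at least 11.3-fold higher (3.65 ± 0.29) and SYCP3, of the synaptonemal complex, at least 2.76-fold (2.41 ± 0.15). MEI1, needed for meiotic recombination, was 2.89-fold higher (1.53 ± 0.23). The cohesin subunit SMC1B was called on its deposited values (1.57 ± 0.14), but lay under background in CEF and was at least 1.48-fold higher, a bound under the 2-fold minimum. Among members not called, the cohesin subunit STAG3 differed by 0.21 ± 0.18. The meiotic MutS homologue MSH4 differed by 0.43 ± 0.15, or -0.32 as the mean of its probe sets.

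Pluripotency genes were higher in PGC for 12 of 21 measured members, higher in CEF for 1 and not called for 8 (camera adjusted p = 0.00027; adjusted p = 0.22 with an estimated correlation; 12 and 1 adjusted over the list alone). EPCAM, an adhesion molecule of stem and epithelial cells that is also in the epithelium list, was at least 347-fold higher (9.53 ± 0.14). The transcription factors SOX3 (8.16 ± 0.14), OTX2 (7.29 ± 0.15, at least 107-fold) and SALL4 (5.77 ± 0.13) were higher too, SOX3 by 286-fold and SALL4 by 54.6-fold. SOX2, related to SOX3, was not called and differed by -0.09, or 0.89 after spike-in scaling and 0.062 without CEF replicate 1. KLF2, a zinc finger factor that is also regulated by blood flow in endothelium, was higher in CEF (-3.46 ± 0.18).

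By the rule for naming genes, which leaves out probe sets shared between transcripts and provisional symbols, the 12 genes with the largest differences towards PGC comprised DAZL, EPCAM, DDX4, KIT, SOX3, DMRT1 and those that follow. The rule left out CLDN1 (9.04) and ESRP2 (8.15, at least 102-fold), each on a shared probe set, and C8orf22 (7.76), which exceeded some of the 12. ENS-3 had the largest difference (10.63 ± 0.17, at least 824-fold). DNMT3B, a de novo DNA methyltransferase, was at least 419-fold higher (8.83 ± 0.15), ELAVL2, a neuronal-type RNA-binding protein, at least 212-fold (8.30 ± 0.12). PPP1R14C, an inhibitor of protein phosphatase 1, was at least 159-fold higher (8.29 ± 0.12). TTC39A (7.90 ± 0.16) and DMRTB1 (7.62 ± 0.13, at least 132-fold), a relative of DMRT1, completed them. The 12 towards CEF were POSTN, LGALS1A, LUM, S100A6, DCN, ANXA1, COL12A1, CCDC80, CALD1, INHBA, MMP2 and CCN2, with log2 differences between -10.27 and -8.53. LGALS1A, a galectin, differed by -10.16 ± 0.18 (at least 1079-fold). The matrix protein CCDC80 differed by -8.76 ± 0.12 (at least 296-fold) and MMP2, a gelatinase, by -8.59 ± 0.17. CCN2, the connective tissue growth factor, was 369-fold higher (-8.53 ± 0.10). The largest adjusted p among the 12 genes of either direction was 5.8e-08, for ANXA1.

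**Figure D2:**
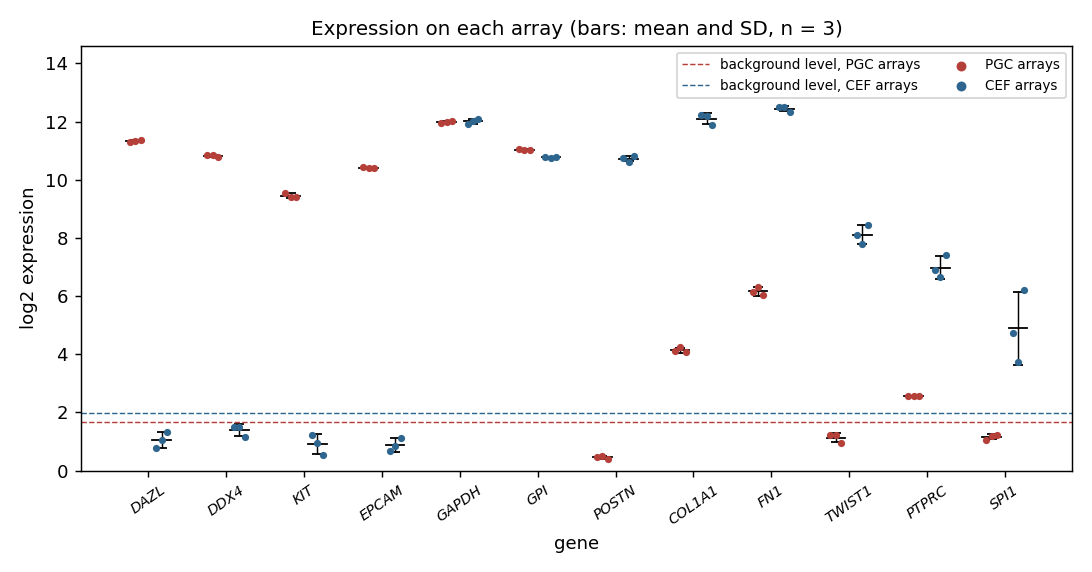
Log2 expression of 12 genes on each of the 3 PGC arrays (red) and 3 CEF arrays (blue), with black bars for mean and SD and dashed lines for the background levels of 1.68 in PGC and 1.97 in CEF. DAZL, DDX4, KIT and EPCAM lie below background on the CEF arrays, POSTN, TWIST1 and SPI1 lie below it on the PGC arrays, and GAPDH lies at almost the same level in the cell types with the deposited scaling and 0.96 higher in PGC after spike-in scaling.

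Extracellular matrix genes were higher in CEF for 39 of 47 measured members, or 40 adjusted over the list alone, with a list median of -4.10 (camera adjusted p = 3.5e-14; adjusted p = 0.055 with an estimated correlation). The collagen-binding proteoglycans LUM (-10.05 ± 0.24) and DCN (-9.39 ± 0.13) were at least 514-fold and 617-fold higher, and COL12A1, a collagen that associates with type I fibrils, was 463-fold higher (-8.85 ± 0.16). COL1A2, the partner chain of COL1A1, differed less (-4.14 ± 0.09, 17.6-fold), and FN1, fibronectin, was 78.1-fold higher (-6.29 ± 0.09), a size that saturation would understate, since its CEF mean of 12.44 lay at the highest values of the CEF arrays (12.36 to 12.51). Against them, 3 members were higher in PGC, namely the basement membrane proteins NID1 (1.68 ± 0.14), FBLN2 (1.20 ± 0.23) and LAMB1 (1.09). FBLN2 came to 0.92, under the 2-fold minimum, without CEF replicate 2, and LAMB1 to 0.96 after centring on the 75th percentile.

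Fibroblast and mesenchyme markers were higher in CEF for 21 of 33 measured members and in PGC for 0, and 12 were not called (camera adjusted p = 9.8e-09; adjusted p = 0.055 with an estimated correlation; 21 adjusted over the list alone). S100A6, a calcium-binding protein, was at least 697-fold higher (-9.87 ± 0.13) and ANXA1, annexin A1, at least 369-fold (-9.11 ± 0.28). The mesenchymal transcription factors TWIST1 (-6.97 ± 0.19) and PRRX2 (-6.72 ± 0.14) were at least 85.9-fold and 53.1-fold higher. VIM, an intermediate filament protein, was 8.35-fold higher in CEF (-3.06 ± 0.06) and stood at 8.84 in PGC, far above background. After spike-in scaling 3 members were called in PGC and 20 in CEF.

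Actin cytoskeleton and contractile genes were higher in CEF for 23 of 26 measured members, with 0 higher in PGC (camera adjusted p = 3.5e-14; adjusted p = 0.068 with an estimated correlation; 23 adjusted over the list alone). They included CALD1, caldesmon, 420-fold higher (-8.71 ± 0.22), TAGLN, transgelin, 293-fold (-8.20 ± 0.15), and the LIM-domain proteins CSRP2 (-7.61 ± 0.14) and FHL2 (-6.45 ± 0.17, at least 79.0-fold). Leukocyte genes were also higher in CEF for 14 of 25 measured and in PGC for 3, and muscle genes for 9 of 29 and 2. Both stand beside all groups higher in CEF as a measured fact.

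HOX genes, which set position along the body axis, were higher in CEF for 14 of 29 measured members and in PGC for 0, with a list median of -0.95 that turned to 0.02 after spike-in scaling. Under that scaling 13 members were called in CEF. The list was called by camera (adjusted p = 2.7e-06; adjusted p = 0.064 with an estimated correlation; 14 adjusted over the list alone). HOXC9 (-4.99 ± 0.23), HOXB3 (-4.50 ± 0.18), HOXA7 (-4.47 ± 0.21) and HOXA9 (-4.14 ± 0.15) had the largest differences, each with its PGC level under background. They were at least 17.0-fold, 10.5-fold, 19.1-fold and 10.4-fold higher.

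**Figure D3:**
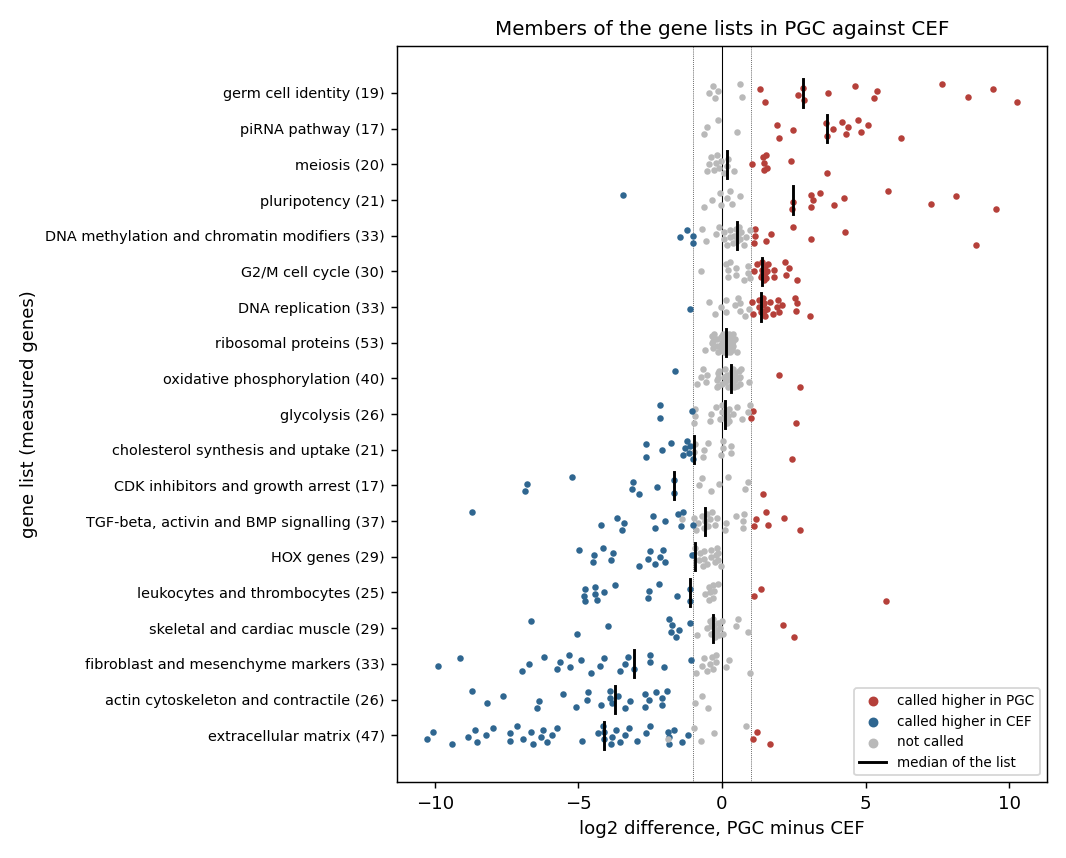
Log2 difference, PGC minus CEF, of every measured member of 19 gene lists, with members called higher in PGC in red, in CEF in blue and the others in grey, list medians as black bars and dotted lines at the 2-fold minimum. The list medians run from 3.66 for the piRNA pathway to -4.10 for extracellular matrix, and after scaling to the bacterial spike-ins those of the HOX, TGF-beta and muscle lists turned to the PGC side, as that of glycolysis turned to the CEF side after centring on the 75th percentile.

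FGF signalling genes went both ways, 8 of 29 measured higher in PGC and 8 in CEF, with a median of -0.22 that turned to 0.75 after spike-in scaling, when 11 were called in PGC and 4 in CEF. The list was not called (camera adjusted p = 0.63; adjusted p = 0.66 with an estimated correlation; 8 and 8 adjusted over the list alone). In PGC, FGF13, an intracellular FGF homologue, was at least 50.6-fold higher (6.81 ± 0.16) and the receptor FGFR3 was 26.4-fold higher (4.72 ± 0.15). In CEF, the immediate early factor EGR1 was at least 103-fold higher (-6.89 ± 0.16) and DUSP5, a nuclear ERK phosphatase, 26.9-fold (-4.75 ± 0.21). SPRED1, a feedback inhibitor, was 2.51-fold higher in CEF (-1.33 ± 0.14), and the receptor FGFR2 was not called (0.67 ± 0.12). As the mean of its probe sets FGFR2 was called higher in PGC (1.26, adjusted p = 1.1e-05), as it was after spike-in scaling.

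Among 37 measured TGF-beta, activin and BMP genes, 12 were higher in CEF, or 13 adjusted over the list alone, and 6 in PGC, with a median of -0.60 that turned to 0.37 with 12 called in PGC and 8 in CEF after spike-in scaling (camera adjusted p = 0.015; adjusted p = 0.16 with an estimated correlation). INHBA, the activin A subunit, was at least 413-fold higher in CEF (-8.69 ± 0.15), and the ligands TGFB3 (-4.21 ± 0.14) and TGFB2 (-3.46 ± 0.11) and the latency protein LTBP1 (-3.65 ± 0.07) were higher there as well. The activin receptor ACVR2B (2.72 ± 0.22) and the ligand BMP7 (2.17 ± 0.14, at least 4.05-fold) were higher in PGC.

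WNT genes were higher in CEF for 11 of 33 measured members and in PGC for 7, with a median of -0.26 that turned to 0.71 with 13 called in PGC and 5 in CEF after spike-in scaling (camera adjusted p = 0.22, not called; adjusted p = 0.38 with an estimated correlation; 7 and 11 adjusted over the list alone). The ligand WNT9A (-4.99 ± 0.23) and the receptors FZD2 (-3.08 ± 0.19) and FZD1 (-2.67 ± 0.14) were higher in CEF. The secreted WNT antagonist SFRP2 (3.98 ± 0.10) and the nuclear effector LEF1 (1.71 ± 0.28) were higher in PGC. CTNNB1, beta-catenin, was not called at -0.63 ± 0.05, or 0.34 after spike-in scaling. In the IGF axis 5 of 17 measured genes were higher in CEF, IGFBP4 (-4.20 ± 0.10), IGF1 (-2.36 ± 0.24, at least 3.36-fold), IGFBP2 (-2.26 ± 0.15), IGFBP3 (-1.93) and IGF1R (-1.40). The 4 higher in PGC were IRS2 (2.58 ± 0.15), an adaptor of insulin and IGF receptors, the RNA-binding protein IGF2BP3 (2.04 ± 0.13), IGFBP7 (1.06) and IGF2BP1 (1.01). The calls of IGFBP7 and IGF2BP1 ended with quantile normalization (0.996 and 0.94) and centring on the 75th percentile (0.94 and 0.89). That of IGF2BP1 also ended with an offset before the logarithm (0.82) and without PGC replicate 1 (0.95), PGC replicate 3 (0.90) or CEF replicate 2 (0.79). The IGF list was not called (camera adjusted p = 0.53; adjusted p = 0.59 with an estimated correlation; 4 and 5 adjusted over the list alone), and its median of -0.14 turned to 0.84 after spike-in scaling, when 8 members were called in PGC and 3 in CEF.

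Most measured cell division genes were called higher in PGC, though neither of their 2 lists was called with an estimated correlation. In the G2/M list 19 of 30 measured members were higher in PGC, or 29 after spike-in scaling, and 0 in CEF (camera adjusted p = 7.4e-08; adjusted p = 0.32 with an estimated correlation; 19 adjusted over the list alone). They were led by the spindle checkpoint kinase TTK (2.62 ± 0.36), the mitotic kinesin KIF11 (2.33 ± 0.11), ECT2 (2.21 ± 0.18), which directs cytokinesis, and the kinetochore protein NUF2 (2.20 ± 0.20). In the DNA replication list 21 of 33 were higher in PGC (camera adjusted p = 8.7e-07; adjusted p = 0.38 with an estimated correlation; 21 and 1 adjusted over the list alone). The largest differences were those of thymidylate synthase TYMS (3.07 ± 0.13), the clamp loader subunit RFC3 (2.60 ± 0.32), the polymerase subunit POLA1 (2.56 ± 0.14) and the origin factor MCM10 (2.55 ± 0.21). The primase subunit PRIM2 was the 1 member higher in CEF (-1.11 ± 0.31). This call ended after spike-in scaling (-0.14), with an offset before the logarithm (-0.93), without CEF replicate 1 (-0.72) and without PGC replicate 1, 2 or 3 (adjusted p = 0.055, 0.050 and 0.056).

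Of 17 measured CDK inhibitors and growth arrest genes, 9 were higher in CEF and 1 in PGC (camera adjusted p = 0.0039; adjusted p = 0.19 with an estimated correlation; 1 and 9 adjusted over the list alone). CDKN2B, a CDK4/6 inhibitor (-6.85 ± 0.28), and CDKN2A (-6.80 ± 0.21) were at least 106-fold and 91.7-fold higher in CEF. CDKN1A, the p21 inhibitor, was 37.3-fold higher (-5.22 ± 0.15) and the antiproliferative factor BTG2 8.67-fold (-3.12 ± 0.11). RBL1, a relative of the retinoblastoma protein, was 2.71-fold higher in PGC (1.44 ± 0.19). After spike-in scaling 4 members were called in PGC and 7 in CEF.

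DNA methylation and chromatin genes were higher in PGC for 9 of 33 measured members and in CEF for 4 (camera adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation, and 0.062 after spike-in scaling; 9 and 4 adjusted over the list alone). After DNMT3B came JARID2, a partner of Polycomb repressive complex 2 (4.28 ± 0.13), MBD3 of the NuRD complex (3.10 ± 0.14) and the histone H3 lysine 9 methyltransferase SUV39H2 (2.46 ± 0.13). The dioxygenase TET2 (-1.44 ± 0.16), the deacetylase HDAC4 (-1.23 ± 0.12), the glycosylase TDG (-1.02) and MBD2 (-1.01) were higher in CEF. After spike-in scaling 25 members were called, each of them higher in PGC. The calls of TDG and MBD2 also ended without PGC replicate 1 (-0.99 each), that of TDG without CEF replicate 3 (-0.96) and that of MBD2 without CEF replicate 1 (-0.96) and with array weights (-0.995).

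Cholesterol synthesis and uptake genes were higher in CEF for 10 of 21 measured members and in PGC for 1, with a median of -0.98 that came to 0.00 after spike-in scaling, when 4 members were called in PGC and 3 in CEF (camera adjusted p = 0.0026; adjusted p = 0.38 with an estimated correlation; 1 and 10 adjusted over the list alone). SC5D (-2.64 ± 0.22), FDPS (-2.64 ± 0.10) and LSS (-2.10 ± 0.15), enzymes of the pathway, were higher in CEF. FDFT1, squalene synthase, went the other way and was 5.36-fold higher in PGC (2.42 ± 0.10).

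Lists of central metabolism were not called. Glycolysis had 3 of 26 measured genes higher in PGC and 3 in CEF (camera adjusted p = 0.55; adjusted p = 0.72 with an estimated correlation; 3 and 3 adjusted over the list alone), with a median of 0.12 that turned negative after centring on the 75th percentile. The counts in PGC and CEF became 14 and 2 after spike-in scaling, 1 and 6 after that centring and 1 and 4 with quantile normalization. PDK1, a kinase that inhibits pyruvate dehydrogenase (2.59 ± 0.09), FBP1 (1.08 ± 0.25), a gluconeogenic enzyme, and the lactate transporter SLC16A1 (1.01) were higher in PGC. ENO2 (-2.17 ± 0.19), HK1 (-2.15 ± 0.11) and PFKP (-1.04), enzymes of the pathway, were higher in CEF. FBP1 lost its call without CEF replicate 2 (0.84), with quantile normalization (0.99), after centring on the 75th percentile (0.96) and with an offset before the logarithm (0.92). SLC16A1 lost it with quantile normalization (0.96), after that centring (0.88) and without PGC replicate 1 (0.98) or CEF replicate 3 (0.93). ENO1 differed by 0.19 ± 0.03. The tricarboxylic acid cycle had 2 of 20 genes higher in each cell type, MDH1 (1.56 ± 0.08) and SUCLG2 (1.45 ± 0.10) in PGC and the isocitrate dehydrogenases IDH1 (-2.99 ± 0.20) and IDH2 (-1.16 ± 0.13) in CEF (2 and 2 adjusted over the list alone). After spike-in scaling 11 members were called in PGC and 1 in CEF. MDH2 differed by 0.30 ± 0.10. The list had a median of 0.17, or 1.15 after spike-in scaling, and a mean of -0.01 (camera adjusted p = 0.56; adjusted p = 0.60 with an estimated correlation).

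Oxidative phosphorylation had 40 measured genes, with NDUFS4 (2.72 ± 0.17) and NDUFA5 (2.00 ± 0.13) higher in PGC and NDUFS3 (-1.65 ± 0.17) higher in CEF. All 3 encode subunits of complex I (list: camera adjusted p = 0.061; adjusted p = 0.51 with an estimated correlation; 2 and 1 adjusted over the list alone). After spike-in scaling the list was called at an adjusted p of 0.0051, with 27 members called, each of them higher in PGC. COX4I1 differed by 0.47 ± 0.05 and ATP5G3, matched through a synonym, by -0.15 ± 0.05, or 0.82 after spike-in scaling. In the list of the pentose phosphate pathway and nucleotide synthesis 6 of 17 measured genes were higher in PGC and 1 in CEF, with 10 called after spike-in scaling, each higher in PGC, and 4 and 2 after centring on the 75th percentile (camera adjusted p = 0.38; adjusted p = 0.66 with an estimated correlation; 6 and 1 adjusted over the list alone). The purine enzyme GART (2.28 ± 0.18), RPIA (1.75 ± 0.12) of the pentose phosphate pathway, the pyrimidine enzyme UMPS (1.63 ± 0.12) and ADSS2 (1.07 ± 0.11) were higher in PGC. ADSS2 came to 0.93 without CEF replicate 2 and to 0.95 after centring on the 75th percentile. PAICS, also of purine synthesis, was 2.83-fold higher in CEF. PGD was not called at -0.84 ± 0.07, or 0.13 after spike-in scaling.

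Of 53 measured ribosomal protein genes, limma called 0 in either direction, 0 adjusted over the list alone as well, and 34 had an unadjusted p under 0.05, 27 towards PGC and 7 towards CEF. Their median difference was 0.13, and camera called the list towards PGC (adjusted p = 0.037; adjusted p = 0.59 with an estimated correlation). That call ended without PGC replicate 3 (adjusted p = 0.051) and CEF replicate 2 (adjusted p = 0.082), and also with the mean of probe sets (0.52), with no intensity trend (0.17) and without dim probe sets (0.13). After centring on the 75th percentile the adjusted p was 0.57, and the median came to 0.01, or to 1.11 after spike-in scaling, when 37 members were called in PGC.

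Innate antiviral and interferon genes were higher in CEF for 10 of 32 measured members, or 11 adjusted over the list alone, and in PGC for 2, with a median of -0.75 that turned to 0.22 with 8 called in PGC and 2 in CEF after spike-in scaling (camera adjusted p = 0.014; adjusted p = 0.38 with an estimated correlation). The interferon regulatory factor IRF2 (-2.66 ± 0.14) and LOC770612 (-2.12 ± 0.26), matched to IFITM3 through a doubtful synonym, were higher in CEF. So was IFNGR2, a chain of the interferon gamma receptor (-1.70 ± 0.09). IFNGR1, the other chain (1.95 ± 0.16, at least 2.95-fold), and IRF8, an interferon regulatory factor of blood cells (1.18 ± 0.14), were higher in PGC. Heat shock and unfolded protein response genes were higher in PGC for 7 of 29 measured members and in CEF for 4 (camera adjusted p = 0.73, not called; adjusted p = 0.72 with an estimated correlation; 7 and 4 adjusted over the list alone). The counts became 14 and 2 after spike-in scaling and 6 and 6 after centring on the 75th percentile. The list median of -0.03 turned to 0.94 after spike-in scaling and to 0.017 without CEF replicate 1, and camera's direction turned to PGC without CEF replicate 2 (adjusted p = 0.89). The chaperones DNAJA1 (2.11 ± 0.12) and HSP90AB1 (1.68 ± 0.13) were higher in PGC, and HSP90AA1 was 2.83-fold higher there. HSPB1 (-6.43 ± 0.14), a small heat shock protein, was 86.3-fold higher in CEF, with the stress factor ATF3 (-3.40 ± 0.20), SDF2L1 (-1.55) and HSPB9 (-1.44). HSPA8 differed by 0.23 ± 0.07.

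Markers of other cell types that the cultures could hold were measured too. Leukocyte and thrombocyte genes were higher in CEF for 14 of 25 measured members, with a median of -1.12 that came to -0.15 with 3 called in PGC and 11 in CEF after spike-in scaling (camera adjusted p = 0.00060; adjusted p = 0.39 with an estimated correlation; 3 and 14 adjusted over the list alone). LAPTM5 (-4.78 ± 0.38, at least 25.4-fold), a lysosomal protein of leukocytes, and F13A1 (-4.77 ± 0.22, at least 14.5-fold), a coagulation factor of macrophages and platelets, were among the members higher in CEF. PTPRC, the pan-leukocyte antigen CD45, differed by -4.43 ± 0.20. In PGC, SH2D6 (5.70 ± 0.35), matched to the list's BLNK through a doubtful synonym, CYBB (1.35 ± 0.43) and MYB (1.10) were higher. CYBB and MYB lost their calls without each of PGC replicates 1 to 3 and CEF replicates 1 and 2 (adjusted p between 0.053 and 0.13), and MYB also after centring on the 75th percentile (0.98) and with an offset before the logarithm (0.92). Without CEF replicate 1 the list had 1 member higher in PGC and 13 in CEF.

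Erythroid genes were higher in PGC for 3 of 16 measured members and in CEF for 2 (camera adjusted p = 0.39, not called; adjusted p = 0.51 with an estimated correlation; 3 and 2 adjusted over the list alone). The median of -0.27 turned to the PGC side after spike-in scaling, when 3 members were called in PGC and 1 in CEF. EPB41 (3.32 ± 0.15), a protein of the membrane skeleton, FECH (1.93 ± 0.14), of haem synthesis, and CA2 (1.80 ± 0.33), a carbonic anhydrase, were higher in PGC. ALAS1 (-2.72 ± 0.13) and the transferrin receptor TFRC (-1.63 ± 0.14) were higher in CEF. ALAS1 entered the list only through a doubtful synonym match to ALAS2 and need not mark erythroid cells. Of the 5 measured globins limma called 0, with 2 at an unadjusted p under 0.05, and HBA1 had the highest mean, 3.87 in PGC and 4.26 in CEF.

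Of 21 measured endothelial genes, 7 were higher in CEF and 1 in PGC (camera adjusted p = 0.059, not called; adjusted p = 0.38 with an estimated correlation; 1 and 7 adjusted over the list alone). The list was called towards CEF without CEF replicate 2 (adjusted p = 0.036), with the mean of a gene's probe sets (0.018) and after spike-in scaling (0.011). Under that scaling 4 members were called in PGC and 6 in CEF, its median turned from -0.28 to 0.69, and camera's direction is relative to the other genes. The ETS factors ERG (-5.99 ± 0.23, at least 48.6-fold) and FLI1 (-3.92 ± 0.22) and the lymphatic receptor LYVE1 (-3.85 ± 0.16, at least 6.72-fold) were higher in CEF, and SOX7 (3.88 ± 0.17, at least 7.46-fold), a vascular transcription factor, in PGC. SOX17 was not called (0.66 ± 0.28) but was without CEF replicate 3 (1.02). ESAM differed by -0.08 ± 0.14, or 0.90 after spike-in scaling and 0.018 without CEF replicate 1. Muscle genes were higher in CEF for 9 of 29 measured members and in PGC for 2, with a median of -0.32 that turned to 0.65 with 5 called in PGC and 3 in CEF after spike-in scaling (camera adjusted p = 0.036, 0.052 with quantile normalization and 0.28 without dim probe sets; adjusted p = 0.23 with an estimated correlation; 2 and 9 adjusted over the list alone). The myosin heavy chain MYH15 was at least 67.0-fold higher (-6.64 ± 0.25), the skeletal actin ACTA1 33.1-fold (-5.05 ± 0.11) and the myosin light chain MYL4 15.7-fold (-3.97 ± 0.27) in CEF. MYL3 (2.50 ± 0.22, at least 4.95-fold) and troponin C, TNNC1 (2.13 ± 0.16), were higher in PGC.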

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

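All tests of explanations in this part were chosen after the results were seen. Among control transcripts, which the comparison of genes leaves out, the bacterial hybridisation spike-ins were lower on the PGC arrays. The difference was -0.97 over the 21 probe sets of bioB, bioC and bioD. In rising order of level it was -1.10 for bioB, -1.08 for bioC, -0.67 for bioD and -0.13 for cre. These spike-ins were taken to be added in fixed amounts after labelling, and unequal addition was not examined. A single scaling factor per array as the whole cause is argued against by the gap of 0.44 between the differences of bioD and bioB, which such a factor would make equal. A larger share of mRNA in the total RNA of PGC was the 1 biological explanation tested. It would lower only the poly-A spike-ins, which were taken to be added to total RNA. Under these assumptions it is argued against by a ratio of 0.82 between the hybridisation spike-in difference and that of the poly-A spike-ins at their 3′ end. A normalization that depends on the level may contribute, since the difference shrank by 0.42 from bioC to bioD, though by only 0.019 from bioB to bioC. Saturation as the cause of the step to bioD is argued against, since bioD lay at least 2.86 below the highest value of each array, and it stays open for the step from bioD to cre.

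The 12 probe sets at the 3′ end of the poly-A spike-ins were lower on the PGC arrays by a log2 difference of -1.19. The 12 at the 5′ end were lower by -0.30, with single probe sets there between -0.93 and 0.25. This smaller value at the 5′ end depended on 1 array. The 5′ mean was 4.02 on CEF replicate 1, against 5.56 and 5.27 on CEF replicates 2 and 3 and 4.65 in PGC.

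The 12 probe sets at the 5′ end of the poly-A spike-ins were lower on the array of CEF replicate 1 than on the other CEF arrays by -1.39, against -0.28 at the 3′ end, while the 5′ and 3′ probe sets of actin, ef1a and gapdh differed by -0.53 and -0.03.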

How the results depend on the processing

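With treat against a 2-fold difference 5664 probe sets (3245 higher in PGC, 2419 in CEF) and 2684 genes (1401 and 1283) were called, because the threshold is stricter by construction. With no minimum fold the counts were 18797 probe sets (9721 and 9076) and 7997 genes (4179 and 3818). Scaling to the bacterial spike-ins, chosen after seeing the data, gave 17324 probe sets (15563 and 1761) and 6866 genes (5938 and 928), because it shifts the PGC arrays upward by construction. Of the 9469 called probe sets it kept 77.7%, against 95.7% with quantile normalization and 93.9% after centring on the 75th percentile, with 56.0% and 53.3% of calls higher in PGC. With an estimated correlation camera called 0 lists (0 and 0), and fry called 31 (13 and 18), since fry does not compare a list with other genes.

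Leaving out one array gave 9297 to 9703 probe sets (5466 to 5821 in PGC, 3831 to 3933 in CEF), 4176 to 4295 genes (2227 to 2353 and 1913 to 1960) and 16 to 17 lists (6 to 7 and 10 to 11). Signs turned for GAPDH without PGC replicate 1 (0.00095) and CEF replicate 3 (range of the arrays left out -0.0567 to 0.028) and as the mean of its probe sets (0.0050), for ESAM (range -0.18 to 0.018) and SOX2 (range -0.24 to 0.062) without CEF replicate 1, and for camera's direction of the heat shock list without CEF replicate 2 (median -0.064, range -0.17 to 0.017). As the mean of a gene's probe sets MSH4 turned to -0.32, TF to -0.062 and UBAP2L2 to -0.087. Under spike-in scaling GAPDH turned to 0.96, ESAM to 0.90, CTNNB1 to 0.34, ATP5G3 to 0.82, PGD to 0.13, SOX2 to 0.89, HBA1 to 0.58 and HBAD to 0.51. These genes turned by construction, because that scaling subtracts the spike-in difference of -0.97 from each log2 difference. Camera's direction of the epithelium list, towards PGC with the deposited values, turned to CEF under that scaling (camera adjusted p = 0.96), although the list median was 0.92. The cause of the other changes of sign was not tested. Over the alternatives, 3176 values of named genes kept direction and call, 33 gained a call, 115 lost it and 16 turned, and for lists the numbers were 498, 18, 26 and 2.

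The replicate numbers do not pair the arrays, since deviations of same-numbered arrays correlated at -0.036, -0.014 and 0.0088 and no PGC array correlated best with the CEF array of its number. A replicate block gave 9498 probe sets and kept all 9469, and among named genes and lists it changed only the call of HINTW (adjusted p = 0.015). Genes near the background levels of 1.68 and 1.97 are limited by signal, with 1538 genes at background in both cell types.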

Other observations

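All tests of explanations in this part were chosen after the results were seen. Epithelial, neural, skeletal and liver genes added contrasts beyond the groups described so far. Epithelial genes were higher in PGC for 6 of 22 measured members and in CEF for 3 (6 and 3 adjusted over the list alone), with a median of -0.05 that turned to 0.92 with 10 called in PGC and 3 in CEF after spike-in scaling. CLDN1, a tight junction protein, was 525-fold higher in PGC (9.04 ± 0.13). KRT7 (-6.77 ± 0.27) and KRT14 (-4.10), keratins, and PKP2 (-6.13 ± 0.15), of desmosomes, were higher in CEF. Neural and neural crest genes were higher in PGC for 7 of 26 measured members and in CEF for 1 (7 and 1 adjusted over the list alone), with a median of 0.09 that turned to -0.03 after centring on the 75th percentile, and came to 1.06 with 13 called in PGC after spike-in scaling. ELAVL4, a neuronal RNA-binding protein, was 83.6-fold higher in PGC (6.39 ± 0.13), as were FOXD3 (3.42 ± 0.24, at least 10.6-fold), which is also in the pluripotency list, and the melanosome protein PMEL (2.77 ± 0.21). NES, nestin, was higher in CEF (-2.29 ± 0.18). FABP7 was not called (0.78 ± 0.24) but was without CEF replicate 3 (1.07). By camera the lists were not called, with an adjusted p of 0.64 and 0.38, and adjusted p = 0.66 and 0.47 with an estimated correlation.

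Cartilage and bone genes were higher in CEF for 5 of 22 measured members and in PGC for 2 (2 and 5 adjusted over the list alone), with a median of -0.08 that turned to the PGC side with 8 called in PGC and 4 in CEF after spike-in scaling (camera adjusted p = 0.32; adjusted p = 0.53 with an estimated correlation). The bone protein SPP1 (-4.86 ± 0.35), the cartilage proteins COMP (-3.77 ± 0.25), COL11A1 (-2.93 ± 0.19) and HAPLN1 (-1.39) and RUNX2 (-3.06 ± 0.14), a regulator of bone formation, were higher in CEF. The call of HAPLN1 ended without CEF replicate 3 (-0.83) and without each PGC array (adjusted p between 0.054 and 0.072). LECT1 (1.92 ± 0.30, at least 3.44-fold), matched to CNMD through a synonym, and SOX9 (1.29 ± 0.14), a regulator of cartilage and gonads, were higher in PGC. The cartilage collagen COL2A1 differed by 0.15 ± 0.11. Gonadal and liver somatic genes were higher in CEF for 3 of 21 measured members and in PGC for 2 (2 and 3 adjusted over the list alone), with a median of -0.26 that turned to the PGC side with 6 called in PGC and 3 in CEF after spike-in scaling (camera adjusted p = 0.47; adjusted p = 0.53 with an estimated correlation). CUBN (-3.51 ± 0.19, at least 9.15-fold), an endocytic receptor, TTR (-3.50 ± 0.61), a thyroid hormone carrier, and SOX8 (-2.41 ± 0.23) were higher in CEF. The gonadal hormone AMH (1.28 ± 0.12) and transferrin, TF (1.15 ± 0.07), were higher in PGC, calls that ended for AMH (0.081) and turned for TF (-0.062) with the mean of probe sets.

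The 14 leukocyte genes higher in CEF had a median difference of -3.91. This difference was 13.7 times the gap of 0.28 between the background levels. The ratio cannot decide whether the higher background of the CEF arrays was their cause. A call already required a difference of at least 1, which is over that gap. Whole blood remaining in the CEF cultures at harvest is argued against because 0 of 5 measured globins were called higher in CEF. By limma 2 had an unadjusted p under 0.05. These were HBA1 and HBAD, with an adjusted p of 0.030 and 0.021 at differences of -0.39 and -0.46. Their differences turned to 0.58 and 0.51 after spike-in scaling. Whole blood carried in at the start cannot be excluded by the globins, since red cells could have been lost before the harvest at passage 2. Of the 14 genes 10 (71.4%), PTPRC, SPI1 and CSF1R (not called without CEF replicate 3, -0.67, or without any 1 of the PGC arrays) among them, shared the order replicate 3, 1, 2 from highest to lowest CEF array, against 22.8% of the 1933 genes higher in CEF. This is consistent with a hypothesis that a varying share of leukocyte-lineage cells, such as macrophages, was present in the CEF cultures, and expression of some of these genes by fibroblasts stays open and was not tested.

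HINTW, on the W chromosome that only female birds carry, stood at 11.67, 2.18 and 6.62 on the arrays of CEF replicates 1, 2 and 3 and at most at 1.76 on the PGC arrays. Its difference of -5.16 ± 1.90 was not called (limma adjusted p = 0.052) but was called without CEF replicate 2 (-7.48, adjusted p = 0.0028), after centring on the 75th percentile or spike-in scaling, with array weights, with a replicate block and without dim probe sets. A general upward shift of the array of CEF replicate 1 is argued against by its median difference of 0.030 from the other CEF arrays. Of 4 measured W-linked genes 3 were highest there by over 2 on the log2 scale. These were HINTW and, matched through synonyms, LOC374195 (5.76 against 0.86 and 1.00) and SPIN1L (5.27 against 0.56 and 0.52). Embryo pools of unequal sex make-up, as a hypothesis, could give this contrast of CEF replicate 1 with CEF replicate 2. They do not readily account for CEF replicate 3, where HINTW was intermediate while LOC374195 and SPIN1L lay under background. HINTW lay 5.04 lower there than on CEF replicate 1. With equal shares of 5 embryos, 1 female would give a smaller gap. The shares of cells from single embryos were not measured. Whether PGC lack HINTW whatever their sex cannot be told apart from cultures of male cells only. HINTW exceeded background on the PGC arrays by at most 0.11, and the sex is not given in the sources used here. Male pools by chance would need 20 male embryos in each of the 3 replicates, but a loss of female cells during culture was not examined.

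The W-linked list had 4 measured genes, too few for camera, and 1 was called, UBAP2L2 (1.13 ± 0.27, at least 2.16-fold higher in PGC; 1 and 0 adjusted over the list alone). It stood above background on each PGC array, at 3.21, 3.34 and 2.69, and was lowest, at 1.38, on the array of CEF replicate 1, where HINTW was highest. It lost its call without CEF replicate 1 (0.85) and with an offset before the logarithm (0.86), and turned to -0.087 as the mean of its probe sets. In all, 13 probe sets were over 4 higher on the log2 scale on the array of CEF replicate 1 than on the mean of the other CEF arrays, 3 of them for HNRNPKL and 1 for UBE2R2L, against 0 for CEF replicate 2 and 2 for CEF replicate 3.

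Of the 689 probe sets without the chicken prefix 3 were called, all higher in CEF, and they carry no gene name here. One stood at 10.25 ± 0.31 (SD, n = 3) in CEF and 1.23 ± 0.09 in PGC, at least 380-fold higher (-9.02 ± 0.17). Another from the same sequence record differed by -2.65 ± 0.55, with 3.49, 5.04 and 6.15 on the CEF arrays, and the third by -1.05 ± 0.14. The third lay under background in PGC and was at least 1.85-fold higher in CEF, a bound under the 2-fold minimum.

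There were too few splits of the 6 arrays, 10 with the real one, for a share under 0.05. The real split gave 9469 probe sets, 4227 genes and 17 lists, in each case the highest of the splits (1 of 10). The highest of the other splits gave 0 probe sets, 0 genes and 15 lists. Every other split mixed the cell types in both groups, so their difference entered the spread within groups. Counts of 0 were therefore likely beforehand and are no support for the real split. Camera with the preset correlation called 8 to 15 lists in these splits, although 0 genes were called.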
